A study of Rattus norvegicus with 20 samples.

How the data were processed

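Tissue RNA of 20 rats, 4 per group, was hybridized to one-colour (Cy3) Agilent rat arrays with 8 arrays per slide, 1 array per animal per the labels. The deposited scanner files hold a background-subtracted, detrended signal per feature in units of intensity, which the authors obtained with Agilent Feature Extraction 10.7.3.1 and did not scale between arrays. The deposited value table holds a ratio, each array's signal divided by its own median (a median of 1 in every column), not log transformed. Of its 20 columns 12 match the scanner file of the same sample and 8, all STW5 samples, match the scanner file of the other dose with the same replicate number. Which of these assignments is right stays unknown, as do the animals' pairing across groups and any step before scanning that the labels do not state. Scanner files were used under the labels they were deposited with, and the value table served as an alternative.

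Sham arrays lay on slide 1, untreated and low-dose STW5 arrays on slide 2, and high-dose STW5 and omeprazole arrays on slide 3. Of 58717 non-control features, spots of the same probe were averaged on the log2 scale without spots that Feature Extraction marked as outliers (263 to 377 features per array), giving 30367 probes, and 11 probes with no spot left on some array were dropped. Probes were matched to genes of the GRCr8 annotation by accession (18005), symbol (2671) or synonym (549), or named only by the array file (1928), and 7214 had no gene. A probe was kept if at least 50% of its spots were well above background on at least 4 arrays, and each gene was represented by its probe with the highest mean, giving 16095 probes and 13596 genes. Each array was scaled by subtracting its 75th percentile on the log2 scale. Group means of the share of features well above background were 64.9% ± 1.70 (SD, n = 4) for sham, 67.7% ± 1.87 for untreated, 63.5% ± 1.34 for low-dose, 68.3% ± 2.01 for high-dose and 67.9% ± 0.980 for omeprazole arrays, and the median signal of an array was 63.5 to 142 units.

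The design fixed before the data were examined counted 20 arrays as 20 samples. The counting of near-identical arrays as one sample, its measure and its limit of 1.5 were chosen after seeing the data. For each of 190 pairs of arrays the spread of single-spot differences between the arrays was divided by that between spots of a probe on one array, over 3430 bright probes. Arrays of a group with a ratio under 1.5 counted as one RNA. Low-dose replicates 1 and 2 had a ratio of 1.38, against at least 2.71 for other pairs within groups and 2.32 for pairs between groups, and were averaged, which left 19 samples. The counts with all 20 arrays, as first designed, are given beside those of the comparisons with low-dose STW5.

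All 5 groups were fitted together in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the package data.table) with lmFit and eBayes, with 14 residual and 2.78 prior degrees of freedom, and 10 comparisons were taken as contrasts. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, and the median standard error of a log2 change was 0.245 (0.264 with low-dose STW5), so differences much under 1 are often missed with these numbers of arrays. Values in the text are log2 changes ± SE, unless a group was not well above background, where the fold is a lower bound against the background level. The comparisons, the tests, the alternatives other than those named as added, the rule for naming genes and 36 gene lists of 748 genes, 606 of them measured, were fixed at that time as well. On the lists limma's camera was run with the preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Return toward sham is minus the slope through the origin of the drug effect on the surgery effect, in percent, with the untreated arrays split into pairs so that the 2 effects share no untreated array.

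Genes are named by rule: in the surgery comparison the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, no overlap of arrays between groups and an established symbol. In each other comparison they are the 6 and 6 largest, filled up to 6 in all by the smallest p where fewer passed. Up to 4 members with the smallest p were added from each list described, which are the lists called and 10 fixed ones. Some genes that the rule names are not reported here, and no others take their place. Genes from outside the slide 3 set were chosen after the values were seen.

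At these sizes, of 100 simulated genes changed by log2 1 and 100 by 2, 58% and 88% were called in untreated against sham. In low-dose against untreated these were 47% and 82%. Far more genes were called in the real data, whose shares may differ. A simulated set without change gave 0 calls in all 10 comparisons. Its noise was independent between genes, unlike that of the arrays, so false calls in real data stay unknown. A simulated return of 50%, 0% and 100% was measured as 46.7%, 0.292% and 93.9%. The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the deposited value table, other filters on dim probes, the mean of the probes, a fit of only the 2 groups compared, the slide as a block, trend and robust settings, array weights, a log2 change of at least 1, an estimated correlation, a replicate block and leaving out each sample. Fits with 20 arrays and fits without the slide 3 genes were added after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Blood, which the labels also mention, has no arrays here.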

Results

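RNA of oesophageal tissue from Wistar rats was measured on one-colour Agilent microarrays in 5 groups of 4 arrays. The groups were sham-operated rats, rats with surgically induced reflux oesophagitis and no drug, and operated rats given a low dose of STW5, a high dose of STW5 or omeprazole. STW5 is a liquid combination of herbal extracts used for functional disorders of the gut, and omeprazole is a proton pump inhibitor that blocks gastric acid secretion. The drugs were given for 7 days before surgery and for 10 days after it, and then the oesophagus was taken. Between 61.5% and 70.5% of the features of an array were well above background, 0 features were saturated, and the 75th percentile of the signal lay between 563 and 1078 units. Arrays of the same group correlated across probes with r between 0.956 and 0.995, a value across probes that are not independent replicates. Replicates 1 and 2 of low-dose STW5 differed only 1.38 times as much as spots of one array do and were averaged, a choice made after seeing the data. So 19 samples and 13596 genes were compared, and low-dose STW5 has n = 3.

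The first comparison, untreated oesophagitis against sham surgery, shows what the reflux operation changed in the oesophagus. The largest rises included chemokine and cytokine genes. The neutrophil-attracting chemokines Cxcl3, Cxcl2 and Cxcl1 rose by log2 8.76 ± 2.05, 8.65 ± 2.22 and 6.96 ± 1.44 (SE, n = 4 and 4, adjusted p = 0.00438, 0.00743 and 0.00205). Il1b, which encodes the cytokine interleukin 1 beta, rose by 7.93 ± 1.62 (adjusted p = 0.00191). The macrophage chemokine gene Ccl3 rose by 7.46 ± 1.67 and Spp1, which encodes osteopontin, by 7.21 ± 1.47 (adjusted p = 0.00329 and 0.00187). Lcn2, a gene for an iron-sequestering protein of neutrophils and stressed epithelium, rose by 5.88 ± 1.11 and Fcnb, which encodes a lectin of myeloid cells, by 6.28 ± 0.99 (adjusted p = 0.00115 and 0.000400). The stretch-induced muscle genes Ankrd2 and Ankrd1 rose by 6.73 ± 1.06 and 6.42 ± 1.00 (adjusted p = 0.000400 and 0.000380). In each of these genes all 4 untreated arrays lay above all 4 sham arrays, which the rule for naming genes requires. In the rat assembly GRCr8, Il1b lies on chromosome 3, 137030200 to 137036581, Cxcl2 on chromosome 14, 17465210 to 17467255 and Lcn2 on chromosome 3, 36078432 to 36081851.

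Marker lists of leukocytes other than B and plasma cells were called higher at the preset correlation. 20 of 20 measured markers of macrophages and monocytes rose (20 adjusted over the list alone, adjusted p = 3.73e-14). Among them were Tyrobp (3.60 ± 0.47), Cd14 (3.87 ± 0.52), Mrc1 (2.80 ± 0.35) and Aif1 (2.86 ± 0.43). Of the neutrophil markers 12 of 15 rose (13 adjusted over the list alone, adjusted p = 9.15e-07). Camp, the gene of the antimicrobial peptide cathelicidin, stood at 5.82 ± 0.86 and Csf3r, the receptor gene for granulocyte colony-stimulating factor, at 5.23 ± 1.06. Among chemokines 12 of 19 rose (14 adjusted over the list alone, adjusted p = 2.29e-06). Among them were the eosinophil attractant Ccl11 (5.62 ± 0.75), the monocyte attractants Ccl7 (5.07 ± 0.78) and Ccl2 (4.36 ± 0.78), and Ccl4, which was at least 22.8-fold higher because the sham arrays were near background. Pro-inflammatory cytokines rose at 7 of 16 genes and fell at 1 (7 and 2 adjusted over the list alone, adjusted p = 0.0132). Tnf stood at 4.24 ± 0.70, Csf3 at 3.31 ± 0.61, Osm at 2.89 ± 0.52 and Il18 at 1.58 ± 0.26. T and NK cell markers rose at 11 of 14 genes (12 adjusted over the list alone, adjusted p = 4.66e-06). Among them were Cd4 (2.55 ± 0.54) and Nkg7 (2.49 ± 0.51). Mast cell and eosinophil markers rose at 3 of 16 (3 adjusted over the list alone, adjusted p = 0.0164). One of them was Tpsab1, a mast cell tryptase gene (2.34 ± 0.60). Over all genes 2035 of 13596 rose, a share close to that of this list. As the mean of its centred genes on the log2 scale, the list reached 1.60 in the highest sham array. The highest untreated array lay at 1.10, so the 2 groups overlap in it. Complement and acute phase genes rose at 13 of 16 (15 adjusted over the list alone, adjusted p = 5.02e-08). Among them were Hp (5.63 ± 0.82), A2m (3.93 ± 0.53), C5ar1 (3.41 ± 0.54) and C3ar1 (3.23 ± 0.53). Antigen presentation genes rose at 12 of 15 (13 adjusted over the list alone, adjusted p = 5.55e-08). Among them were the class II loading genes RT1-DMb (2.75 ± 0.37) and RT1-DMa (2.38 ± 0.34). The B and plasma cell list was not called (adjusted p = 0.620), with 1 of 6 genes rising and 1 falling. With an estimated correlation the adjusted p of the 22 lists called in this comparison lay between 0.225 and 0.592, so 0 of them were called by camera that way, against 6 of the 36 lists at an unadjusted p under 0.05.

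Tissue remodelling and vessel genes rose as well. Matrix protease genes rose at 16 of 19 (18 adjusted over the list alone, adjusted p = 8.04e-09). Among them were Mmp3 (3.63 ± 0.66), Ctss, which encodes cathepsin S (3.12 ± 0.52), and Mmp19 (2.24 ± 0.39). Fibrillar matrix genes rose at 13 of 24 (15 adjusted over the list alone, adjusted p = 1.12e-07). Tenascin C (Tnc) stood at 3.93 ± 0.61, versican (Vcan) at 3.04 ± 0.43, the collagen cross-linking enzyme gene Lox at 2.85 ± 0.45, and Thbs1 was at least 15.9-fold higher. Endothelial genes rose at 11 of 15 (13 adjusted over the list alone, adjusted p = 2.25e-06). The leukocyte adhesion genes Selp, Sele and Icam1 stood at 4.15 ± 0.84, 3.46 ± 0.50 and 2.44 ± 0.32. Immediate early genes rose at 10 of 16 (11 adjusted over the list alone, adjusted p = 9.50e-05). Among them were Socs3 (3.33 ± 0.62), Fos (2.47 ± 0.52) and Egr2 (1.83 ± 0.25). Apoptosis genes rose at 10 of 17 and fell at 2 (11 and 3 adjusted over the list alone, adjusted p = 0.00135). Fas was among those that rose (1.28), but its other probe stood at -0.46. Bak1, a pro-apoptotic gene, stood at 1.33 ± 0.23. Cell cycle genes rose at 7 of 24 (7 adjusted over the list alone, adjusted p = 0.00546). Aurka stood at 1.08 ± 0.32 and Rrm2 at 1.23 ± 0.37. The estimated-correlation adjusted p of these 6 lists lay within the same 0.225 to 0.592.

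Transcripts of squamous epithelium, muscle and oxidative phosphorylation fell. Terminal differentiation genes of squamous epithelium fell at 19 of 27 (22 adjusted over the list alone, adjusted p = 3.08e-06, and adjusted p = 0.370 with an estimated correlation). They included the suprabasal keratin gene Krt1 (-3.06 ± 0.57, adjusted p = 0.00106), on chromosome 7, 134855311 to 134860537, and Casp14, the caspase gene of cornifying cells (-2.33 ± 0.47). Flg, the gene of the keratin-aggregating protein filaggrin, fell by 3.33 ± 0.95 (adjusted p = 0.0131). Tight junction and desmosome genes fell at 17 of 26 (20 adjusted over the list alone, adjusted p = 2.76e-06, and adjusted p = 0.256 with an estimated correlation). Evpl stood at -1.62 ± 0.37, Cldn23 at -1.43 ± 0.31, Tjp3 at -1.37 ± 0.26 and the tricellulin gene Marveld2 at -1.24 ± 0.24. Basal keratinocyte genes were not called (adjusted p = 0.570), although Col17a1 (-1.21 ± 0.27), Sox2 (-1.31 ± 0.30) and Krt15 (-1.07 ± 0.28) fell. Skeletal muscle genes fell at 15 of 29 and rose at 1 (18 and 1 adjusted over the list alone, adjusted p = 0.000477, and adjusted p = 0.451 with an estimated correlation). The fast-fibre genes Actn3 and Pvalb stood at -2.40 ± 0.37 and -1.52 ± 0.30. Smooth muscle genes fell at 6 of 11 (6 adjusted over the list alone, adjusted p = 0.00759, and adjusted p = 0.451 with an estimated correlation). Lmod1 stood at -2.22 ± 0.51 and Myh11 at -1.92 ± 0.41. Oxidative phosphorylation genes fell at 12 of 25 (15 adjusted over the list alone, adjusted p = 5.37e-05, and adjusted p = 0.451 with an estimated correlation). The changes were small, such as -0.78 ± 0.19 for Ndufs1 and -0.62 ± 0.15 for Uqcrc2. The single genes with the largest falls were Mss51, a regulator of muscle mitochondria (-3.84 ± 0.44, adjusted p = 0.000158), Ttc36 (-3.23 ± 0.68) and the neuromedin B receptor gene Nmbr (-3.23 ± 0.86). Next came the muscle-secreted peptide gene Ostn (-3.02 ± 0.54), the carboxylesterase gene Ces1e (-2.93 ± 0.60) and the antiprotease gene Wfdc12 (-2.92 ± 0.69). Bbox1, the gene for the last enzyme of carnitine synthesis, and Cobl, which encodes an actin nucleator, were at least 5.55-fold and at least 5.27-fold lower (adjusted p = 0.000181 and 0.000290).

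In all, 4475 of 13596 genes changed, 2035 upward and 2440 downward, and 1479 of those that rose and 1524 of those that fell had no overlap between the 4 untreated and the 4 sham arrays. Of all genes, called or not, 1596 lay without overlap above sham and 1723 below it, where chance gives 1.43% of genes in each direction. One sham array, replicate 2, held far more of some inflammatory transcripts than the other shams: its Il1b value was 1.08, against -6.94, -7.22 and -4.97 in replicates 1, 3 and 4, and its Cxcl3 value was 2.65. The size of such rises depends on this array: without it the changes of Cxcl3, Cxcl2, Cxcl1 and Il1b were 11.07, 10.23, 8.19 and 9.79. With signals near background raised to the lowest signal well above it, a measure chosen after the values were seen, they were 8.46, 8.25, 6.41 and 7.58. Camp, Csf3r, Mmp3 and Sele then stood at 5.06, 4.64, 3.09 and 2.69, and of 378 values of named genes over all comparisons these 4 and that of Cxcl1 shrank by more than 0.5, the largest by 0.77. Without replicate 2, 4672 genes changed, and leaving out any other sample of the 2 groups gave 3361 to 4571. With only these 2 groups fitted, which leaves fewer samples, 2263 changed, 1217 upward and 1046 downward, and with array weights 5747. Those weights were 8.93 for sham replicate 3, against 0.39, 0.56 and 0.62 for replicates 1, 2 and 4. No other group shared the slide of the sham arrays, so in every comparison with sham the slide and the group cannot be told apart.

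**Figure D1:**
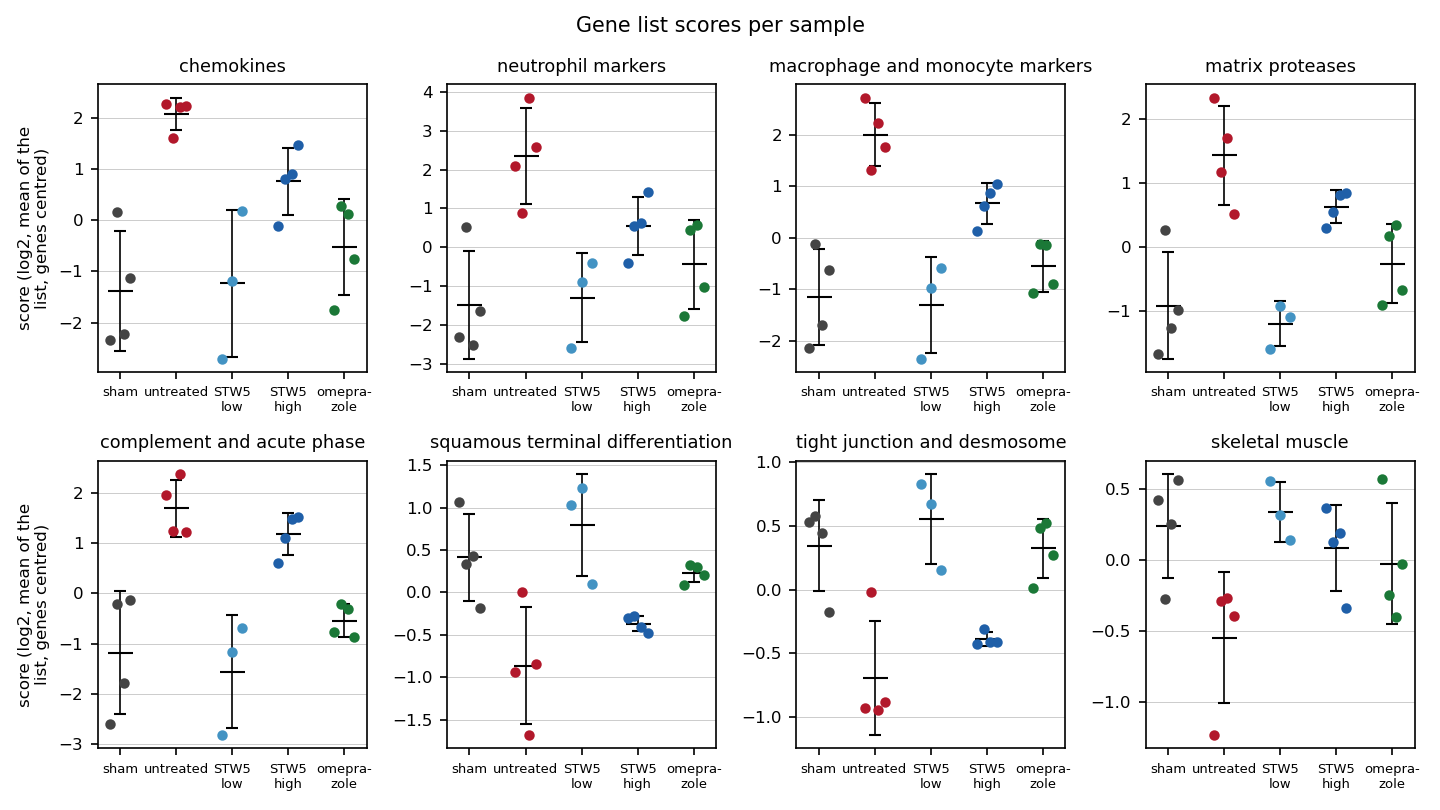
Gene list scores of the 19 samples, as the mean of the list's genes on the log2 scale, each gene centred on its mean, on the y axis and the 5 groups on the x axis, with points for samples and black bars for the mean ± SD. Macrophage markers averaged -1.14 in sham, 2.00 in untreated, -1.30 in low-dose, 0.67 in high-dose and -0.55 in omeprazole arrays, and squamous genes 0.41, -0.87, 0.79, -0.37 and 0.23.

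The drug groups were compared with untreated oesophagitis to see how far each treatment changed the inflamed tissue. STW5 was given at 0.5 ml/kg (called low) or 2 ml/kg (called high). Which arrays are which dose is not settled: the deposited value table holds, in all 8 of its STW5 columns, the scanner values of the other dose. The series description also numbers the 0.5 ml/kg group 3 and the 2 ml/kg group 4, while the sample titles number them the other way. The dose names here follow the scanner files, and under the value table's assignment every value given for one dose belongs to the other. In the low-dose arrays chemokine genes that had risen most with surgery were lower than in untreated arrays. The change was -7.39 ± 2.39 for Cxcl2, -6.81 ± 2.22 for Cxcl3 and -6.05 ± 1.80 for Ccl3 (SE, n = 3 and 4, adjusted p = 0.0231, 0.0236 and 0.0150). It was -5.46 ± 1.75 for Il1b and -5.77 ± 1.20 for Lcn2 (adjusted p = 0.0220 and 0.00160). The collagenase gene Mmp13 was at least 46.0-fold lower (adjusted p = 0.00576), while Fcnb and the myeloid resistin-like gene Retnlg stood at -5.80 ± 1.07 and -5.78 ± 1.10 (adjusted p = 0.000736 and 0.000889). Krt1 rose by 3.75 ± 0.62 and Mss51 by 3.59 ± 0.47 (adjusted p = 0.000410 and 0.000179). So did the serpin gene Serpina12 by 3.41 ± 0.71, the membrane mucin gene Muc15 by 3.34 ± 0.43 and the alcohol dehydrogenase gene Adh6a by 3.24 ± 0.53. Cyp1a1, the classic target gene of the aryl hydrocarbon receptor, was at least 5.04-fold higher (adjusted p = 0.00896), and lies on chromosome 8, 66991940 to 66998014.

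Leukocyte lists other than B and plasma cells (adjusted p = 0.982, 2 of 6 genes higher and 1 lower) fell in the low-dose arrays at the preset correlation. With an estimated correlation camera called 0 of the 19 lists of this comparison (adjusted p between 0.176 and 0.569), against 8 at an unadjusted p under 0.05. Macrophage markers fell at 20 of 20 (20 adjusted over the list alone, adjusted p = 7.11e-14). Cd14 stood at -4.27 ± 0.56, Mrc1 at -3.68 ± 0.38, Tyrobp at -3.49 ± 0.51 and the growth factor receptor gene Csf1r at -2.88 ± 0.41. Chemokines fell at 14 of 19 (15 adjusted over the list alone, adjusted p = 1.33e-06). Among them were Ccl11 (-5.26 ± 0.81), Ccl7 (-4.95 ± 0.85) and Ccl4 (-4.00 ± 0.55). Neutrophil markers fell at 10 of 15 (11 adjusted over the list alone, adjusted p = 4.15e-06). Among them were Camp (-5.10 ± 0.93) and Trem1 (-4.83 ± 1.01). T and NK cell markers fell at 8 of 14 (11 adjusted over the list alone, adjusted p = 4.69e-05). Mast cell and eosinophil markers fell at 9 of 16 (13 adjusted over the list alone, adjusted p = 1.38e-05). Tpsab1 stood at -2.99 ± 0.64, and the eotaxin receptor gene Ccr3 was at least 2.08-fold lower. Complement genes fell at 14 of 16 (15 adjusted over the list alone, adjusted p = 2.16e-09). Antigen presentation genes fell at 12 of 15 (12 adjusted over the list alone, adjusted p = 8.52e-08). Matrix proteases fell at 16 of 19 (18 adjusted over the list alone, adjusted p = 1.67e-09). Fibrillar matrix genes fell at 18 of 24 (19 adjusted over the list alone, adjusted p = 8.27e-11). Endothelial genes fell at 13 of 15 (14 adjusted over the list alone, adjusted p = 7.08e-09). Examples are Hp (-4.93 ± 0.88), RT1-DMb (-3.06 ± 0.40), Mmp14 (-2.80 ± 0.46), Vcan (-3.34 ± 0.46) and Icam1 (-2.63 ± 0.35). Cell cycle genes fell at 12 of 24 (18 adjusted over the list alone, adjusted p = 2.13e-06). Rrm2 stood at -1.52 ± 0.40 and Pcna at -1.04 ± 0.29. Immediate early genes fell at 6 of 16 (6 adjusted over the list alone, adjusted p = 0.00150). Apoptosis genes fell at 8 of 17, with 3 rising (10 and 3 adjusted over the list alone, adjusted p = 0.00158). Cytokines were not called (adjusted p = 0.0564): Tnf (-3.50 ± 0.75) and Il18 (-1.81 ± 0.28) fell while Il36b, an epithelial cytokine gene, rose (2.07 ± 0.46).

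Squamous, junction and skeletal muscle genes were higher with the low dose. Squamous differentiation genes rose at 23 of 27 (23 adjusted over the list alone, adjusted p = 3.54e-07). Casp14 stood at 2.69 ± 0.50, Pof1b at 2.34 ± 0.43 and Krt78 at 2.26 ± 0.43. Tight junction genes rose at 19 of 26 (19 adjusted over the list alone, adjusted p = 3.71e-06). The occludin gene Ocln stood at 1.82 ± 0.27 and Tjp3 at 1.87 ± 0.28. Skeletal muscle genes rose at 12 of 29 (13 adjusted over the list alone, adjusted p = 0.00189), with Pvalb at 1.81 ± 0.33. Oxidative phosphorylation genes rose at 9 of 25 (13 adjusted over the list alone, adjusted p = 0.00132), with Ndufa4 at 0.86 ± 0.21. These 4 lists are among the 19, and 0 of them were called with an estimated correlation. The smooth muscle list was not called (adjusted p = 0.898): 1 of 11 genes rose, with 2 higher and 1 lower at an unadjusted p under 0.05. Its score averaged -0.38, against -0.63 in untreated and 0.48 in sham arrays. The basal keratinocyte list was not called either (adjusted p = 0.759), with 6 of 20 genes rising and 1 falling. In all 5111 genes changed, 2951 upward and 2160 downward (3935 and 1691 with the normexp background correction). The slide as a block cannot change the count of 5111, as each group lay on 1 slide. With only these 2 groups fitted 2797 genes changed. With all 20 arrays, none averaged, 6066 changed, and with the value table's dose assignment 1294.

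Against untreated oesophagitis, the high-dose arrays differed at fewer genes. Among the largest falls, the defensin gene RatNP-3b was at least 12.3-fold lower (n = 4 and 4, adjusted p = 0.000669), and the fatty acid receptor gene Gpr84 stood at -3.77 ± 0.78 (SE, adjusted p = 0.00764). Camp stood at -3.53 ± 0.86 and Ccl4 at -3.39 ± 0.51 (adjusted p = 0.0189 and 0.000500). The protease gene Mmp7 was at least 10.3-fold and the growth factor gene Vegfb at least 5.66-fold lower (adjusted p = 0.00960 and 0.0206). Cyp1a1 was at least 6.82-fold higher (adjusted p = 0.0119). The other 5 of the 6 largest rises, Pecr (at least 14.7-fold, adjusted p = 2.53e-08), Txnip (4.22 ± 0.30), Tob1 (at least 6.90-fold), Lactb (at least 10.8-fold) and Cox6c-ps1 (3.56 ± 0.22), belong to 176 genes whose 8 arrays of slide 3, which held only high-dose STW5 and omeprazole, all lay beyond all other samples. For 20 of its 163 higher genes other probes were measured, which shifted by a median of -0.03, against 1.22 for the chosen probes of the same genes. Outside that set, and chosen after the values were seen, Myh13, a myosin gene (3.12 ± 0.60), Tcf21, a mesenchymal transcription factor gene (2.65 ± 0.34), Barx1, a homeobox gene of foregut mesenchyme (2.61 ± 0.74), and Ttc36 (2.58 ± 0.68) rose.

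Macrophage markers fell at 6 of 20 (12 adjusted over the list alone, adjusted p = 9.67e-06). Cd14 stood at -2.57 ± 0.52 and the integrin gene Itgam at -1.85 ± 0.36. Cytokines fell at 4 of 16 (4 adjusted over the list alone, adjusted p = 0.0244). Csf3 stood at -2.71 ± 0.61, Tnf at -2.83 ± 0.70 and Osm at -1.98 ± 0.52. Chemokines fell at 2 of 19, Ccl4 and Ccl2 (-3.04 ± 0.78), with 2 falling and 1 rising adjusted over the list alone (adjusted p = 0.0423). Neutrophil markers fell at 2 of 15, Camp and Mmp8 (-3.12 ± 0.82), with 6 adjusted over the list alone (adjusted p = 0.00207). Matrix proteases fell at 4 of 19 (5 adjusted over the list alone, adjusted p = 0.0124). Fibrillar matrix genes fell at 3 of 24 (3 adjusted over the list alone, adjusted p = 0.0124). Apoptosis genes fell at 3 of 17, with 5 falling and 1 rising adjusted over the list alone (adjusted p = 0.0151). Fas was among the 3 (-1.58), but its other probe stood at 0.55. Hypoxia and glycolysis genes fell at 4 of 16 (6 adjusted over the list alone, adjusted p = 0.00427). The glucose transporter gene Slc2a1 stood at -1.02 ± 0.27. Genes of the Nrf2 antioxidant response fell at 3 of 24, with 6 falling and 1 rising adjusted over the list alone (adjusted p = 0.0244): the haem oxygenase gene Hmox1 (-1.96 ± 0.45), Sod2 (-1.26 ± 0.29) and Txnrd1 (-1.31 ± 0.34). Skeletal muscle genes rose at 3 of 29 (3 adjusted over the list alone, adjusted p = 0.00194), namely Myh2 (1.72 ± 0.44), Pvalb (1.44 ± 0.30) and Myh4 (1.37 ± 0.35). Oxidative phosphorylation genes rose at 2 of 25 (1 adjusted over the list alone, adjusted p = 0.0102). Schwann and enteric neuron genes rose at 1 of 17, Th (0.94 ± 0.18), with 1 adjusted over the list alone (adjusted p = 0.0251). Further lists were called with few or no single members passing. Squamous differentiation was higher (1 of 27, Casp14 at 1.70 ± 0.47, and 0 adjusted over the list alone, against 4 at an unadjusted limma p under 0.05, adjusted p = 0.0244). Smooth muscle was higher (0 of 11, 3 adjusted over the list alone and 3 unadjusted, adjusted p = 0.0139). Called lower were T and NK cell markers (0 of 14, 4 adjusted over the list alone and 4 unadjusted, adjusted p = 0.0135) and cell cycle genes (0 of 24, 0 adjusted over the list alone and 5 unadjusted, adjusted p = 0.0124). So were immediate early genes (0 of 16, 0 adjusted over the list alone and 7 unadjusted, adjusted p = 0.00194). With an estimated correlation the adjusted p of the 17 lists lay between 0.606 and 0.685, and camera called 0, against 2 at an unadjusted p under 0.05.

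Of the inflammatory genes that led the surgery comparison, Cxcl3 (-3.35 ± 2.05, adjusted p = 0.301), Il1b (-1.93 ± 1.62, adjusted p = 0.460) and Lcn2 (-0.85 ± 1.11, adjusted p = 0.650) did not pass between high-dose and untreated arrays. Neither did Krt1 (1.11 ± 0.57, adjusted p = 0.214). In all 1291 genes changed, 698 upward and 593 downward (611 and 1019 with normexp, 521 and 664 with median scaling), and 944 without the slide 3 genes. With the value table's assignment the count was 5109. It was 480 with only these 2 groups fitted, 1782 with array weights, 829, 2037 and 694 without untreated replicate 1, 2 or 3, and 414 and 687 without high-dose replicate 1 or 2. Without untreated replicate 1 the lists called were 6.

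With omeprazole part of the inflammatory genes fell and part of the epithelial genes rose. The change was -6.59 ± 2.22 for Cxcl2 and -5.03 ± 0.75 for Ccl11 (SE, n = 4 and 4, adjusted p = 0.0359 and 0.000270). Fcnb stood at -5.03 ± 0.99, Cxcl1 at -4.97 ± 1.44 and Lcn2 at -4.88 ± 1.11 (adjusted p = 0.00183, 0.0172 and 0.00468). The myeloid receptor gene Cd300c2 was at least 30.7-fold and Ccl4 at least 26.8-fold lower (adjusted p = 0.000610 and 4.69e-06). Il1b (-4.05 ± 1.62, adjusted p = 0.0719) and Cxcl3 (-4.80 ± 2.05, adjusted p = 0.0910) did not pass. Cyp1a1 was at least 22.4-fold higher (adjusted p = 0.000318), Ttc36 rose by 4.00 ± 0.68 (adjusted p = 0.000698) and Mss51 by 3.14 ± 0.44 (adjusted p = 0.000152). Pecr (at least 14.4-fold), Bicdl1 (at least 11.7-fold, but log2 1.24 with its other probe), Tob1 (at least 7.43-fold) and Txnip (3.82 ± 0.30) were the other genes among the 6 largest rises, all from the slide 3 set. Outside that set, and chosen after the values were seen, the albumin gene Alb rose by 3.31 ± 0.80 and the dopamine receptor gene Drd5 by 2.96 ± 0.46, and Syndig1l was at least 5.45-fold higher.

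Camera called 21 lists with omeprazole at the preset correlation and 0 of them with an estimated one (adjusted p 0.330 to 0.631), against 2 at an unadjusted p under 0.05. Macrophage markers fell at 19 of 20 (20 adjusted over the list alone, adjusted p = 1.12e-12). Cd14 stood at -3.31 ± 0.52 and Tyrobp at -3.11 ± 0.47. Chemokines fell at 9 of 19, with 9 falling and 1 rising adjusted over the list alone (adjusted p = 4.68e-05). Neutrophil markers fell at 9 of 15 (10 adjusted over the list alone, adjusted p = 2.16e-05). Camp stood at -4.13 ± 0.86. Complement genes fell at 7 of 16 (12 adjusted over the list alone, adjusted p = 2.45e-06). One of them was Hp (-4.79 ± 0.82). Antigen presentation genes fell at 10 of 15 (11 adjusted over the list alone, adjusted p = 8.15e-06). Matrix proteases fell at 11 of 19 (13 adjusted over the list alone, adjusted p = 2.25e-06). One of them was Mmp3 (-3.59 ± 0.66). Fibrillar matrix genes fell at 9 of 24 (9 adjusted over the list alone, adjusted p = 7.30e-06). One of them was the protease inhibitor gene Timp1 (-3.78 ± 0.72). Endothelial genes fell at 8 of 15 (9 adjusted over the list alone, adjusted p = 0.000397). Immediate early genes fell at 8 of 16 (10 adjusted over the list alone, adjusted p = 8.15e-06), with Ccn1 at -2.53 ± 0.48. Cytokines fell at 6 of 16 and rose at 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0485). Tnf stood at -3.57 ± 0.70 and the receptor antagonist gene Il1rn at -1.39 ± 0.28. T and NK cell markers fell at 3 of 14 (3 adjusted over the list alone, adjusted p = 0.000460). Mast cell and eosinophil markers fell at 3 of 16 (3 adjusted over the list alone, adjusted p = 0.00118), where 1656 of all 13596 genes fell. Hypoxia genes fell at 4 of 16 with 1 rising (6 and 1 adjusted over the list alone, adjusted p = 0.0349). Eno1 was among those that fell (-0.58), but its other probes stood at -0.65 and 0.88. Apoptosis genes fell at 7 of 17 with 1 rising (8 and 1 adjusted over the list alone, adjusted p = 0.00253), the latter being Bcl2, an anti-apoptotic gene (1.14 ± 0.26). Among those that fell, Fas stood at -1.74, but at 0.52 with its other probe.

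Squamous differentiation genes rose at 15 of 27, with 20 rising and 1 falling adjusted over the list alone (adjusted p = 7.50e-05). Among them were the protease inhibitor gene Spink5 (2.04 ± 0.52) and Casp14 (2.01 ± 0.47). Tight junction genes rose at 17 of 26 (18 adjusted over the list alone, adjusted p = 8.15e-06). Among them were Cldn3 (2.01 ± 0.51) and Cldn23 (1.53 ± 0.31). The basal keratinocyte list was not called (adjusted p = 0.162), although Col17a1 (1.24 ± 0.27) and Krt15 (1.03 ± 0.28) rose. Smooth muscle genes rose at 3 of 11 (3 adjusted over the list alone, adjusted p = 0.0292). Oxidative phosphorylation genes rose at 6 of 25 (6 adjusted over the list alone, adjusted p = 0.00227). Skeletal muscle genes rose at 7 of 29 with 2 falling (7 and 2 adjusted over the list alone, adjusted p = 0.0384): the fast myosin gene Myh4 rose (2.38 ± 0.35) while the slow troponin gene Tnnt1 (-2.04 ± 0.52) and the muscle regulator gene Myog (-1.29 ± 0.32) fell. The called lists of this paragraph are among the 21, and 0 of them were called with an estimated correlation. In all 3772 genes changed, 2116 upward and 1656 downward (1469 and 1948 with median scaling), and 3557 without the slide 3 genes. With only these 2 groups fitted 2709 changed. Untreated and omeprazole arrays lay on different slides, as did untreated and high-dose arrays, so slide and treatment cannot be told apart in these 2 comparisons.

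Further lists show signalling, drug metabolism and the neighbouring stomach. Eicosanoid pathway genes went both ways with surgery, 10 rising and 5 falling of 22 (11 and 6 adjusted over the list alone, adjusted p = 0.0229, and adjusted p = 0.256 with an estimated correlation). Pla2g7, a phospholipase gene of macrophages, rose by 3.51 ± 0.47, the thromboxane synthase gene Tbxas1 by 2.37 ± 0.35 and the prostaglandin E synthase gene Ptges by 2.04 ± 0.42, and the prostaglandin E receptor gene Ptger2 was at least 9.12-fold higher. Against untreated arrays the list fell at 12 and rose at 5 genes with low-dose STW5 (13 and 5 adjusted over the list alone, adjusted p = 0.00576, and adjusted p = 0.213 with an estimated correlation). It fell at 6 and rose at 5 with omeprazole (8 and 6 adjusted over the list alone, adjusted p = 0.0388, and adjusted p = 0.330 with an estimated correlation). Pla2g7 stood at -3.28 ± 0.50 and -3.16 ± 0.47. With high-dose STW5 the list was not called (adjusted p = 0.129), although Ptger2 (-2.49 ± 0.40) and Pla2g7 (-1.90 ± 0.47) fell. Interferon response genes rose with surgery at 7 and fell at 1 of 22 (7 and 1 adjusted over the list alone, adjusted p = 0.00318, and adjusted p = 0.452 with an estimated correlation). The antiviral gene Ifit3 stood at 4.39 ± 0.97 and Oas1a at 3.78 ± 0.79. They fell at 11 and rose at 1 with low-dose STW5 (12 and 1 adjusted over the list alone, adjusted p = 4.69e-05, and adjusted p = 0.340 with an estimated correlation). The list fell at 7 and rose at 1 with omeprazole (7 and 1 adjusted over the list alone, adjusted p = 0.0134, and adjusted p = 0.516 with an estimated correlation). The gene that rose was Igtp (0.69), but its other probes stood at -0.51 and -0.79. With high-dose STW5 the interferon list was not called (adjusted p = 0.681): 1 gene rose and 1 fell, against 4 higher and 2 lower at an unadjusted p under 0.05. Sensory and pain genes rose with surgery at 6 and fell at 1 of 14 (6 and 1 adjusted over the list alone, adjusted p = 0.0229, and adjusted p = 0.225 with an estimated correlation). Higher members were the cannabinoid receptor gene Cnr2 (2.97 ± 0.51), the ion channel gene Trpv4 (1.53 ± 0.31) and the substance P receptor gene Tacr1 (1.69 ± 0.46), while the bradykinin receptor gene Bdkrb1 was at least 5.15-fold higher. This list was not called against untreated arrays with low-dose STW5, high-dose STW5 or omeprazole (adjusted p = 0.0564, 0.814 and 0.244). The aryl hydrocarbon receptor and drug metabolism list was called neither with surgery (adjusted p = 0.384) nor with low-dose STW5, high-dose STW5 or omeprazole (adjusted p = 0.381, 0.333 and 0.0865), and members went both ways: of 15 genes 2 rose and 5 fell with surgery, and 5 and 3, 3 and 2, and 6 and 2 did so with these treatments. Cyp1b1, another target gene of the receptor, rose with surgery (1.83 ± 0.36) and fell with the high dose (-1.88 ± 0.36). Beside Cyp1a1, the drug-metabolizing cytochrome gene Cyp2b2 rose by 1.86 ± 0.35, 1.47 ± 0.33 and 2.08 ± 0.33 against untreated arrays with these 3 treatments, and Ahrr, the repressor gene of the receptor, by 1.21 ± 0.25 with the high dose. Gastric glandular genes were not called either (adjusted p = 0.738 with surgery and 0.606, 0.365 and 0.480 with the 3 treatments). Single members that changed were the chloride transporter gene Slc26a9 (-1.04 ± 0.22 with surgery, 0.67 ± 0.22 with omeprazole, and also higher with low-dose STW5, adjusted p = 0.000340), the histidine decarboxylase gene Hdc (-2.26 ± 0.76 with low-dose STW5), the mucin gene Muc6 (0.78 ± 0.20, 0.66 ± 0.19 and 0.96 ± 0.19 with the 3 treatments) and the gastrin gene Gast (0.71 ± 0.18 with omeprazole).

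**Figure D2:**
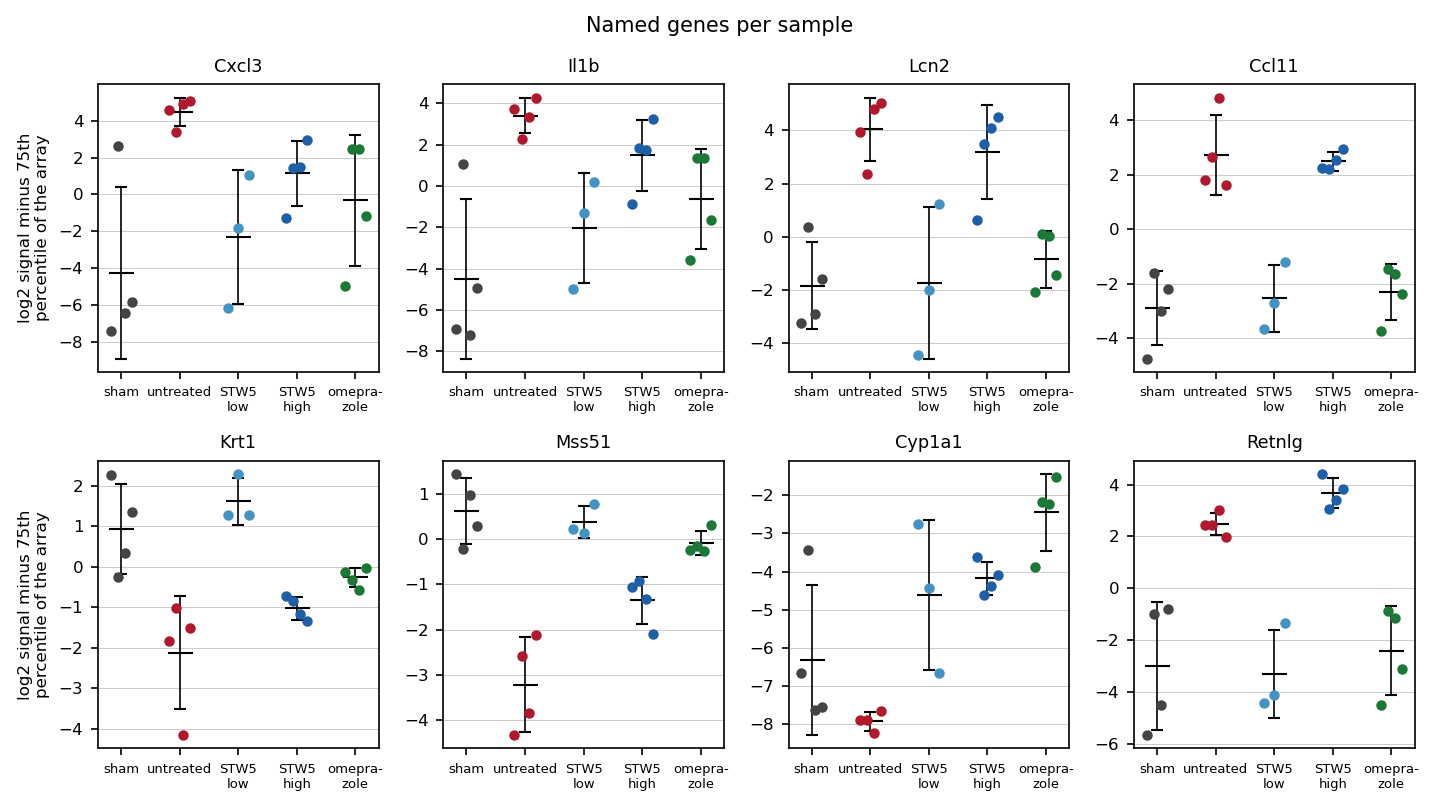
Values of 8 named genes in the 19 samples, as log2 signal minus the array's 75th percentile on the y axis and the 5 groups on the x axis, with points for samples and black bars for the mean ± SD. Cyp1a1 averaged -7.92 in untreated, -4.61 in low-dose, -4.17 in high-dose and -2.45 in omeprazole arrays, and sham replicate 2 lay at -3.44.

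Each drug group was also set against sham surgery, to see what differed from sham-operated tissue under treatment. In low-dose arrays 1 of 13596 genes passed in limma, C8h3orf62, which was 1.19 ± 0.18 higher (SE, n = 3 and 4, adjusted p = 0.0478), against 1083 genes at an unadjusted p under 0.05. With array weights 2590 genes passed, 1501 higher and 1089 lower, so how far low-dose tissue differs from sham depends on the weighting of the arrays. Sham replicate 3 weighed 8.93 there, against 0.39 to 0.62 for the other shams, so that count leans on 1 sham array. The genes with the next smallest p, which did not pass, included the clock gene Per2 (1.48 ± 0.27, adjusted p = 0.168), Serpini1 (-1.17 ± 0.22), Or6b13 (1.12 ± 0.21), Rpap1 (-1.06 ± 0.21) and Atoh7 (1.08 ± 0.21). For 8707 genes (64.0%) the 95% confidence interval of the log2 change lay within 1 either way, so larger differences at the other genes are not excluded by these arrays. Camera called 13 lists, among them smooth muscle (median -0.98, adjusted p = 2.03e-06), cell cycle (median -0.33, adjusted p = 2.03e-06), mast cell and eosinophil (median -1.08, adjusted p = 4.26e-06), endothelial (median -0.66, adjusted p = 4.81e-05) and fibrillar matrix genes (median -0.34, adjusted p = 4.86e-05), all lower. Squamous differentiation was higher (median 0.47, adjusted p = 0.00567). In limma 0 members of these 6 lists passed over all genes. In the order above, 0, 0, 0, 0, 1 and 0 passed adjusted over the list alone, and 6 of 11, 3 of 24, 4 of 16, 4 of 15, 9 of 24 and 0 of 27 had an unadjusted p under 0.05 in the direction of the list. With an estimated correlation the adjusted p of these lists lay between 0.655 and 0.897, 0 were called, and 1 had an unadjusted p under 0.05. The count of genes was 0 without sham replicate 1 or 4 or low-dose replicate 3, 3 without low-dose replicates 1 and 2, and 90 without low-dose replicate 4. It was 0 with all 20 arrays, none averaged, and 1163 with the value table's assignment. Without low-dose replicates 1 and 2 the lists called were 4.

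High-dose arrays were set against sham next. Retnlg was 6.67 ± 1.02 higher (SE, n = 4 and 4, adjusted p = 0.000685), Ccl11 5.38 ± 0.75 (adjusted p = 0.000293), Lcn2 5.03 ± 1.11 (adjusted p = 0.0120) and Ankrd2 4.85 ± 1.06 (adjusted p = 0.0116). The epidermal lipoxygenase gene Alox12e was at least 23.1-fold higher, and Dio2, the gene of a thyroid hormone deiodinase, was higher as well (adjusted p = 4.94e-06 and 0.00696). Bbox1 was at least 4.90-fold lower (adjusted p = 0.00149), and the epithelial surface gene Ly6d (-2.21 ± 0.50), Fstl4 (-2.21 ± 0.49), the ligand gene Wnt16 (-2.17 ± 0.44), Cryba4 (-2.16 ± 0.46) and the plasma cell receptor gene Tnfrsf17 (-1.98 ± 0.48) were lower. Macrophage markers were higher at 13 of 20 (15 adjusted over the list alone, adjusted p = 2.73e-10). Complement genes were higher at 10 of 16 (15 adjusted over the list alone, adjusted p = 1.24e-10). Antigen presentation genes were higher at 8 of 15 (13 adjusted over the list alone, adjusted p = 6.49e-09). Matrix proteases were higher at 7 of 19 (12 adjusted over the list alone, adjusted p = 3.58e-07). Chemokines were higher at 4 of 19 (7 adjusted over the list alone, adjusted p = 4.50e-06). Endothelial genes were higher at 4 of 15 (10 adjusted over the list alone, adjusted p = 2.99e-06). Tight junction genes were lower at 3 of 26 (10 adjusted over the list alone, adjusted p = 1.28e-05). Squamous genes were lower at 2 of 27 (0 adjusted over the list alone, adjusted p = 5.43e-05). These lists were among 14 called, with an adjusted p between 0.289 and 0.805 with an estimated correlation, which left 0 called and 5 at an unadjusted p under 0.05. In all 1162 genes changed, 823 upward and 339 downward (604 and 842 with normexp, 674 and 802 with median scaling), and 834 without the slide 3 genes. The count was 7089 with array weights (sham replicate 3 at 8.93, the other shams at 0.39 to 0.62), 3036 higher and 4053 lower. It was 478 and 418 without sham replicate 1 or 3, and 636, 517 and 405 without high-dose replicate 2, 3 or 4. It was 1 with the value table's assignment.

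In omeprazole arrays 213 genes differed from sham, 211 of them higher. With array weights (sham replicate 3 at 8.93, the other shams at 0.39 to 0.62) 3564 differed, 1827 higher and 1737 lower. With only these 2 groups fitted 142 differed, all higher. The 6 largest rises, Lactb (at least 8.82-fold, adjusted p = 6.05e-09), Hspd1-ps3 (at least 11.3-fold), Txnip (3.35 ± 0.30), Tob1 (at least 5.67-fold), Bicdl1 (at least 7.53-fold, but log2 0.54 with its other probe) and Cox7c (3.06 ± 0.35), all belong to the slide 3 set. Without that set 35 genes changed (71 when sham replicate 2 was left out too). Outside the set, and chosen after the values were seen, the glutamine synthetase gene Glul was 2.52 ± 0.34 higher and Tcf21 at least 3.01-fold higher (n = 4 and 4). The 2 genes that were lower were Ccdc175 (at least 2.62-fold, adjusted p = 0.0220) and Bag5, a co-chaperone gene (-0.73 ± 0.15, adjusted p = 0.0133). Camera called 4 lists: cell cycle (median 0.40, adjusted p = 0.000782), endothelial (median 0.43, adjusted p = 0.0294) and antigen presentation genes (median 0.46, adjusted p = 0.0389) higher, and skeletal muscle genes (median -0.35, adjusted p = 0.0294) lower. In these 4 lists 0 members passed in limma, over all genes or adjusted over the list alone, against 4, 2, 3 and 1 at an unadjusted p under 0.05 in those directions. The adjusted p of all 4 was 0.903 with an estimated correlation. The count of genes was 329 without sham replicate 2. The lists called were 0, 14, 1 and 11 without sham replicate 1, 2, 3 or 4, and 10, 2, 2 and 9 without omeprazole replicate 1, 2, 3 or 4.

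The treatments were compared with each other, first the STW5 doses. Myeloid and matrix genes were higher in the high-dose arrays. Retnlg was 6.99 ± 1.10 higher (SE, n = 4 and 3, adjusted p = 0.000900), Ccl11 5.03 ± 0.81 (adjusted p = 0.00104), the matrix protein gene Spon1 4.47 ± 0.60 (adjusted p = 0.000220, but 2.79 with its other probe) and Txnip, of the slide 3 set, 4.50 ± 0.32. Mmp13 was at least 26.3-fold and Alox12e at least 19.4-fold higher (adjusted p = 0.0221 and 3.09e-05). Krt1 was lower (-2.64 ± 0.62, adjusted p = 0.00834), as were Ctxn3 (-2.28 ± 0.77) and Plcxd2 (-2.23 ± 0.49), and Bbox1, Dcst1 and Angptl6 were at least 3.98-fold, at least 3.46-fold and at least 3.01-fold lower. Complement genes were higher at 13 of 16 (15 adjusted over the list alone, adjusted p = 3.76e-10). Macrophage markers were higher at 15 of 20 (16 adjusted over the list alone, adjusted p = 2.32e-09). Fibrillar matrix genes were higher at 13 of 24 (17 adjusted over the list alone, adjusted p = 2.32e-09). Endothelial genes were higher at 11 of 15 (13 adjusted over the list alone, adjusted p = 9.84e-09). Chemokines were higher at 8 of 19 (9 adjusted over the list alone, adjusted p = 3.00e-05). Squamous genes were lower at 15 of 27 (17 adjusted over the list alone, adjusted p = 5.10e-06). Tight junction genes were lower at 16 of 26 (16 adjusted over the list alone, adjusted p = 3.00e-05). Camera called 17 lists, with an adjusted p of 0.306 to 0.636 with an estimated correlation, 0 called and 5 at an unadjusted p under 0.05. With normexp the medians of 4 of them (T and NK cell, Schwann and enteric neuron, eicosanoid and sensory lists) had the other sign. In all 3254 genes differed, 1457 higher and 1797 lower in the high-dose arrays (1017 and 4422 with normexp, 1243 and 2867 with median scaling). The doses lay on different slides, and with the value table's assignment each of the 12 genes named by rule turns. With all 20 arrays, none averaged, 4728 genes differed, and with array weights 6341. The count was 926, 1406, 2166 and 2109 without low-dose replicates 1 and 2, low-dose replicate 3, high-dose replicate 3 or high-dose replicate 4.

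High-dose STW5 and omeprazole shared a slide and differed at 30 genes, 26 of them higher with STW5. The slide as a block cannot change this count, as each group lay on 1 slide. With only these 2 groups fitted 1173 differed (639 higher and 534 lower), and with array weights 2256 (1065 and 1191), so the count depends on the model. With all 20 arrays, none averaged, it was 39, and with a replicate block added to those 77 (48 and 29). Retnlg was 6.10 ± 1.02 higher (SE, n = 4 and 4, adjusted p = 0.0192), Ccl11 4.79 ± 0.75 (adjusted p = 0.0145) and the slow muscle troponin genes Tnnt1 and Tnnc1 3.13 ± 0.52 and 2.91 ± 0.51 (adjusted p = 0.0192 and 0.0214). Alox12e and Ccr3 were at least 27.7-fold and at least 8.33-fold higher (adjusted p = 7.79e-05 and 0.00407). Prdm1, a transcription factor gene of plasma cells and differentiating epithelium (-1.22 ± 0.24), Helt-ps1 (-1.08 ± 0.19) and Sgo2, a gene of chromosome cohesion (-1.02 ± 0.20), were lower. Of the 14 lists called, complement genes (median 1.39, adjusted p = 8.34e-11) and macrophage markers (median 1.24, adjusted p = 7.22e-10) were higher with STW5 and tight junction genes (median -0.65, adjusted p = 2.52e-06) lower. In limma 0 members of these 3 lists passed over all genes, against 11, 10 and 6 adjusted over the list alone and 12, 12 and 11 at an unadjusted p under 0.05. With an estimated correlation the adjusted p was 0.497 to 0.759, 0 lists were called and 1 had an unadjusted p under 0.05. The count of genes was 12, 5 and 5 without high-dose replicate 2, 3 or 4 and 9, 10 and 6 without omeprazole replicate 2, 3 or 4, and 327 with the value table's assignment. In this comparison 2434 genes had an unadjusted p under 0.05.

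Between low-dose STW5 and omeprazole 328 genes differed, 84 higher and 244 lower in the low-dose arrays (1395 and 213 with normexp, 785 and 234 with median scaling, 124 and 215 with quantile normalization, 1507 and 1223 with array weights, 11 and 172 with only these 2 groups fitted). Tnnt1 and Tnnc1 were 3.01 ± 0.56 and 2.85 ± 0.55 higher with STW5 (SE, n = 3 and 4, adjusted p = 0.00594 and 0.00786), as was the lipid hydroxylase gene Fa2h (1.24 ± 0.24). Ccdc175 was at least 2.74-fold higher. The largest falls, Hspd1-ps3 (at least 11.6-fold), Txnip (-4.10 ± 0.32), RT1-T24-4 (at least 6.68-fold), Pecr (at least 8.55-fold), Lactb (at least 7.35-fold) and Tob1 (at least 4.74-fold), belong to the slide 3 set. Without it 45 genes differed. Outside it, and chosen after the values were seen, Glul (-2.67 ± 0.37), the bone-resorbing protease gene Ctsk (-2.65 ± 0.62) and the vessel growth gene Angpt2 (-2.33 ± 0.41) were lower. Cell cycle genes were lower at 1 of 24 (9 adjusted over the list alone, adjusted p = 1.73e-10). Endothelial genes were lower at 1 of 15 (6 adjusted over the list alone, adjusted p = 1.09e-06). Fibrillar matrix genes were lower at 0 of 24 in limma (9 adjusted over the list alone and 10 at an unadjusted p under 0.05, adjusted p = 3.25e-06). Camera called 12 lists, each with adjusted p = 0.638 with an estimated correlation, which left 0 called and 1 at an unadjusted p under 0.05. The count of genes was 174 without low-dose replicates 1 and 2, 164 and 783 without low-dose replicate 3 or 4 and 210, 175 and 214 without omeprazole replicate 2, 3 or 4, and 30 with the value table's assignment. With all 20 arrays, none averaged, 1136 genes differed. The lists called were 5 without low-dose replicates 1 and 2.

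**Figure D3:**
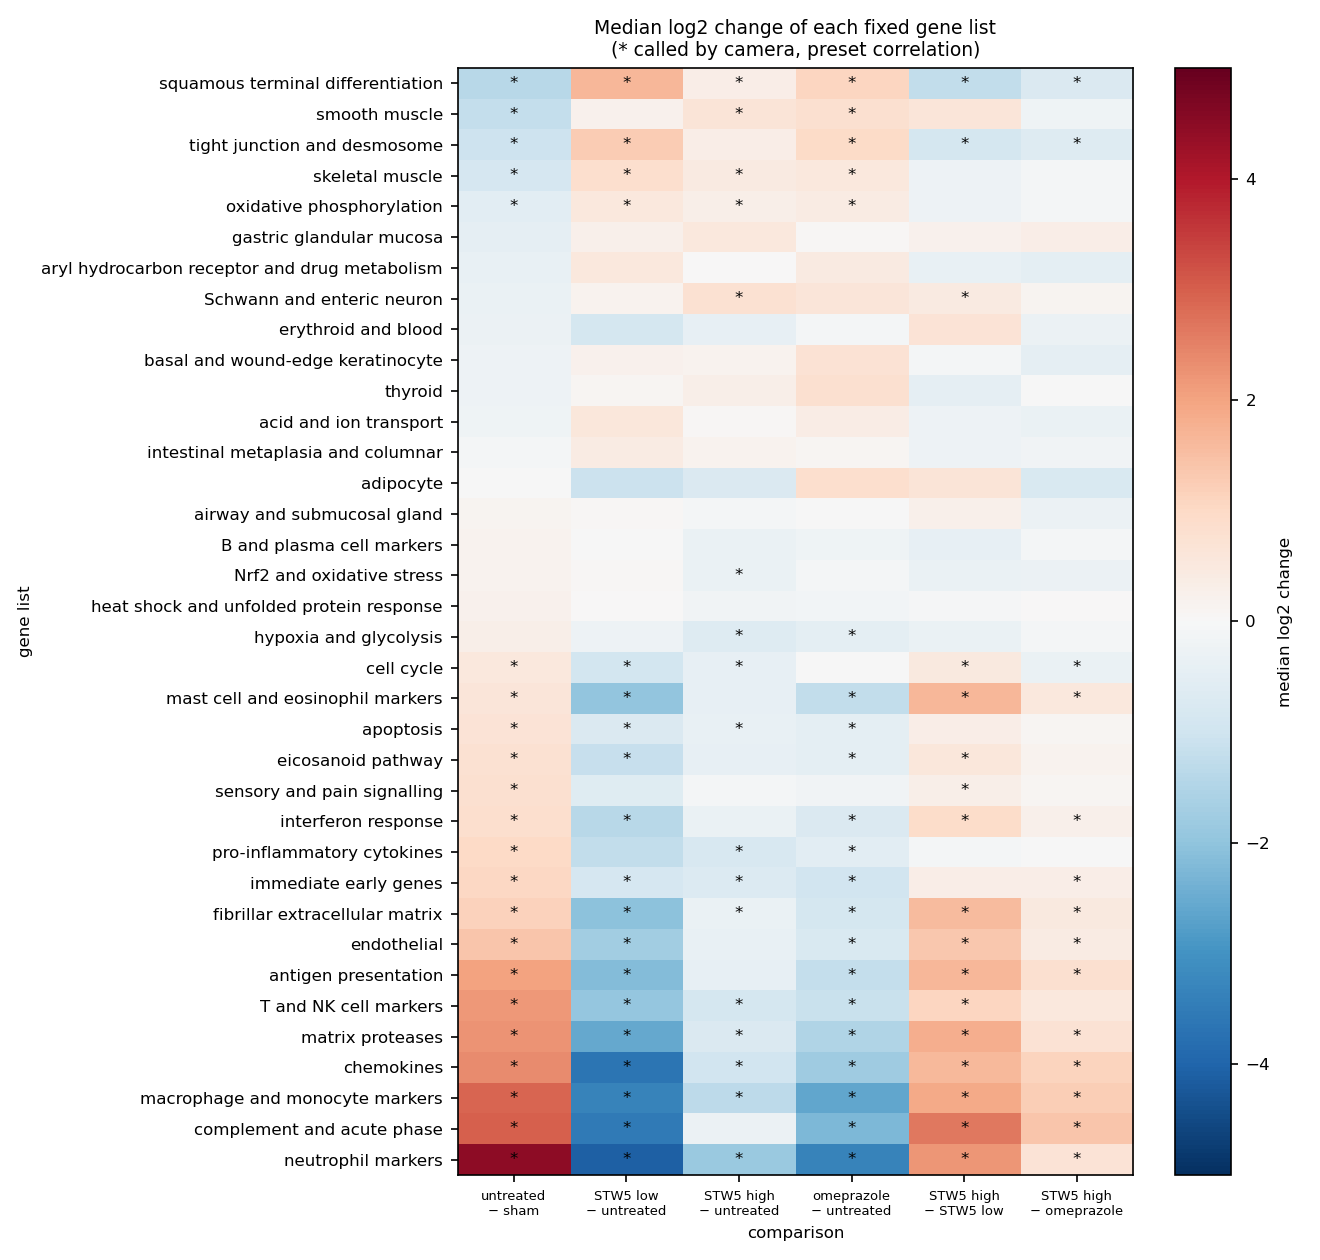
Median log2 change of each of the 36 gene lists (y axis) in 6 comparisons (x axis), in colour from blue (lower) to red (higher), with stars where camera called the list at the preset correlation. With an estimated correlation camera called 0 lists in these comparisons. Macrophage markers had a median of 2.91 in untreated minus sham, and of -3.33, -1.29 and -2.58 in low-dose, high-dose and omeprazole minus untreated.

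How far each drug moved the surgery genes back toward sham was expressed as 1 percentage per drug, from 1077 to 3122 genes that changed with surgery by at least 1 on the log2 scale in a pair of untreated arrays against sham, with the drug effect taken against the other pair. Low-dose STW5 gave 88.1% (range 64.1% to 124.2% over the 6 ways of pairing the untreated arrays), omeprazole 70.4% (47.2% to 106.7%) and high-dose STW5 39.0% (21.5% to 65.9%). A share of 96.8%, 95.4% and 86.2% of the surgery genes moved in the direction of sham with these drugs, against a mean of 54.5%, 45.2% and 54.8% in 16 simulated sets without a drug effect (35.5% to 73.1%, 18.4% to 81.6% and 22.7% to 80.4%). Simulated groups with no treatment effect gave means of 2.58%, -2.79% and 2.17%, and values between -22.3% and 22.6%. With all 20 arrays, none averaged, low-dose STW5 gave 91.7%. The values carry no p, the ranges of the drugs overlap, and with the value table's assignment low-dose STW5 gave 39.0% and high-dose STW5 88.1%.

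**Figure D4:**
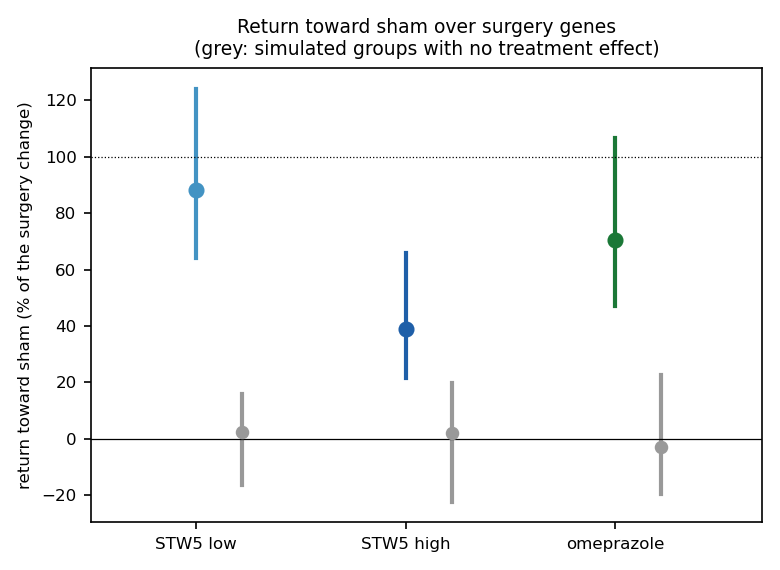
Return toward sham (y axis, percent of the surgery change) for the 3 drug groups (x axis), with the mean over the 6 pairings as a point, their range as a line, and simulated groups without treatment effect in grey. Low-dose STW5 lies at 88.1%, omeprazole at 70.4% and high-dose STW5 at 39.0%, and all simulated values lie between -22.3% and 22.6%.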

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

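Tests of the slide 3 set against treatments and slides, of sham replicate 2 against omeprazole replicate 2 and of its Cyp1a1 value, and of both explanations for the order of the STW5 doses were chosen only after the results were seen. Of 228 tests for a sample far from the others of its group 11 found one, and chance gives about 1 in 20 groups, here 11.4. Omeprazole replicate 1 was lowest in the scores of cell cycle (-0.20, others 0.43 to 0.56), Nrf2 and oxidative stress (-0.28, others -0.01 to 0.04) and thyroid genes (-0.16, others 0.26 to 0.34). Untreated replicate 1 was highest in antigen presentation (1.77, others 0.53 to 0.71) and lowest in skeletal muscle genes (-1.23, others -0.39 to -0.27), and replicate 2 lowest in chemokines (1.60, others 2.20 to 2.26) and highest in tight junction and desmosome genes (-0.023, others -0.94 to -0.88). High-dose STW5 replicate 2 was highest in tight junction and desmosome genes (-0.31, others -0.42 to -0.41). Among single genes, Cxcl3 was highest in sham replicate 2 (2.65, others -7.41 to -5.86), Bbox1 lowest in high-dose replicate 3 (-7.92, others -6.77 to -6.74) and Wfdc12 lowest in untreated replicate 3 (-2.51, others -0.07 to 0.36).

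The effects of the treatments differed by direct test at 3254 genes between high-dose and low-dose STW5, at 30 between high-dose STW5 and omeprazole and at 328 between low-dose STW5 and omeprazole. The 3254 and 328 compare slides as well as treatments, since low-dose arrays lay on slide 2 and the others on slide 3, and without the slide 3 genes they were 3045 and 45. Probes without a gene, 3819 of them, were in no comparison of the report: 559 changed with surgery, and 750, 1074 and 1431 differed from untreated arrays with low-dose STW5, high-dose STW5 and omeprazole. Against sham these were 0, 931 and 843. They were 1195 between the doses, 893 for low-dose STW5 against omeprazole and 0 for high-dose STW5 against omeprazole, which shared a slide. The counts of 0 stand beside 353 and 520 probes at an unadjusted p under 0.05. At 504 of the 3819 probes (13.2%, 502 of them higher) all arrays of slide 3 lay beyond all other samples. Among probes with a gene this held for 219 of 16095 (1.36%). Counts without such probes were not made. Where slide 3 is set against another slide, slide and treatment cannot be told apart.

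The first pattern weighed is the set of 176 genes at which all 8 arrays of slide 3 lay beyond all other samples, among them Txnip, Tob1, Pecr and Lactb, against 6 genes for slide 1 and 12 for slide 2. For 20 of its 163 higher genes, changed transcripts as the cause are argued against by 23 other probes, whose median shift was -0.029 (range -0.40 to 1.19) against 1.22 for the chosen probes, while for the other 156 genes of the set, lower or with no other probe, they stay open. For the higher genes the test of GC content cannot decide. Its range of 35% to 45% GC held 13309 probes, most of those kept, with a median shift of 0.011. Scaling keeps the median shift of so many probes near 0. The 705 probes set apart upward, with and without a gene, shifted by 1.75. Their median GC content was 43.3%, close to the 45% of all probes. For the 13 lower genes GC content was not tested. A difference between slides stays a candidate explanation for the 176 genes and cannot be told apart from the treatments, since each treatment group lay on 1 slide.

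The second pattern is sham replicate 2, whose Il1b, Cxcl3 and Cyp1a1 values lay far above those of the other shams. It showed 43.1% of the surgery effect against the other shams, where replicates 1, 3 and 4 showed -26.9%, -18.2% and 19.8%. A surgery-like injury may explain its Il1b and Cxcl3. Both are among the 2758 surgery genes behind the 43.1%, which was not computed without them. As the cause of its Cyp1a1 value of -3.44 such an injury is argued against, since the highest untreated array lay at -7.645, and replicates 1, 3 and 4 lay at -6.66, -7.63 and -7.55. RNA of a treated animal stays open: 8.33% of 12 genes that part treated from other samples lay nearer to the treated mean (95% interval 0.211% to 38.5%), against 62.5%, 33.3% and 7.69% for the other shams. Its spot spread against omeprazole replicate 2 was 2.32 times that within an array, the lowest between groups but above the 1.5 taken for one RNA, which does not settle whether the 2 share an RNA.

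The third pattern is that low-dose STW5 lay nearer to sham than high-dose STW5, with a return of 88.1% against 39.0%. Exchanged dose labels stay open, since 8 columns of the deposited value table hold the scanner values of the other dose and the series description numbers the dose groups opposite to the sample titles, and nothing in the values says which is right. A difference between slides cannot be told apart from the dose, as the doses lay on different slides, although without the slide 3 genes the doses still differed by 49.4 points. A biological effect of the dose stays open as well and was not tested.

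The samples of each comparison were also divided in all 35 ways into groups of the same sizes. For gene counts, chance is argued against, though not excluded, where only 1 of the 35 splits, the real one, called as many. With 35 splits, and no correction over the 10 comparisons, the test can go no further. Such counts are 4475 genes with surgery (highest other split 1285), and 5111 for low-dose STW5, 1291 for high-dose STW5 and 3772 for omeprazole against untreated (highest others 3742, 1 and 286). The same holds for 1162 and 213 for high-dose STW5 and omeprazole against sham (1 and 190), and for 3254, 30 and 328 between treatments in the order above (1, 0 and 3). The split with 3742 genes set untreated replicates 1, 3 and 4 against the rest. Low-dose STW5 against sham called 1 gene, and 6 splits called as many, so there the splits give nothing against chance. The split of sham replicate 1 with low-dose replicates 1, 2 and 3 against the rest called 1981, which points to a structure of the samples other than their groups. For counts of gene lists the splits give nothing against chance in any comparison. With surgery 3 splits called as many (22, highest other 22). Against untreated 12, 5 and 7 splits did for low-dose STW5, high-dose STW5 and omeprazole (19, 17 and 21, highest others 23, 21 and 22). Against sham it was 19, 17 and 29 (13, 14 and 4, highest others 21, 23 and 21), and 11, 11 and 22 splits between treatments (17, 14 and 12, highest others 23, 21 and 19).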

How the results depend on the processing

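The averaging of low-dose STW5 replicates 1 and 2 in the main settings was itself chosen after seeing the data, as were the fits with 20 arrays, none averaged, without the slide 3 genes, and without sham replicate 2 and the slide 3 genes. Where no reason is given below, the cause was not tested. No gene named by rule changed sign under normexp, quantile or median scaling, and 413, 437 and 435 of their reported values kept direction and side of the threshold, while 32, 8 and 10 lost the threshold. With normexp background the genes changed were 0 for low-dose STW5 and 116 for omeprazole against sham, and 5439 between the STW5 doses. They were 67 for high-dose and 1608 for low-dose STW5 against omeprazole, and 9 lists were called for omeprazole against sham. With quantile normalization these were 0 genes for low-dose STW5 and 10 lists for omeprazole against sham. With median scaling they were 0 genes for low-dose STW5 against sham and 51 and 1019 for high-dose and low-dose STW5 against omeprazole. The counts of 0 stand beside 1083 genes at an unadjusted limma p under 0.05 with the main settings. Median scaling moved the median change of all genes from -0.15 to -0.28 between the STW5 doses, -0.09 to -0.21 and 0.01 to -0.18 for high-dose STW5 and omeprazole against sham, 0.10 to -0.01 for omeprazole against untreated and 0.05 to 0.26 for low-dose STW5 against omeprazole. Normexp moved the same medians to -0.28, -0.18, -0.10, -0.01 and 0.20. The deposited value table exchanges the doses by its construction: 1294 and 5109 genes for low-dose and high-dose STW5 against untreated, 1163 and 1 against sham, 327 and 30 for high-dose and low-dose STW5 against omeprazole, and a return of 39.0% and 88.1%. With it some genes turned. For low-dose STW5 against untreated they were Retnlg 1.21, Ccr3 1.48, Tyms 0.017, Mmp2 0.034, RT1-Da 0.044 and Slc26a9 -0.24. For high-dose STW5 they were Txnip -0.28 against untreated and Retnlg -0.31 against sham, and between the doses Retnlg -6.99, Mmp13 -5.25, Ccl11 -5.03, Alox12e -4.99, Txnip -4.50, Spon1 -4.47, Krt1 2.64, Dcst1 2.33, Ctxn3 2.28, Bbox1 2.28, Angptl6 2.25 and Plcxd2 2.23. Against omeprazole it gave Retnlg -0.89, Ccl11 -0.23, Prdm1 0.59 and Helt-ps1 0.43 for the high dose and Txnip 0.40, RT1-T24-4 0.57 and Pecr 0.027 for the low dose. With the mean of the probes Igtp was -0.21 for omeprazole against untreated, as its probes disagree in sign. Probes of Fas did so too with surgery and with high-dose STW5 and omeprazole against untreated, and those of Eno1 with omeprazole. Without a filter on dim probes 0 genes changed for low-dose STW5 against sham and 5731 between the doses. With probes well above background on all 20 arrays, which tests fewer genes, it was 125 for omeprazole against sham and 12 for high-dose STW5 against omeprazole. With only the 2 groups compared, which leaves fewer samples, 2263 genes changed with surgery, 2797 and 480 with low-dose and high-dose STW5 against untreated, 0 with low-dose STW5 against sham, and 1173 and 183 for high-dose and low-dose STW5 against omeprazole. Trend and robust settings gave 0 for low-dose STW5 against sham. Array weights lay between 0.309 and 8.93, the latter for sham replicate 3, while the other shams had 0.39 to 0.62. They gave 2590, 7089 and 3564 for low-dose STW5, high-dose STW5 and omeprazole against sham, 6341 between the doses and 2256 and 2730 for high-dose and low-dose STW5 against omeprazole. A log2 change of at least 1, a stricter rule, left 2465 genes with surgery, 3010, 687 and 2093 for low-dose STW5, high-dose STW5 and omeprazole against untreated, 722 for high-dose STW5 against sham, 1783 between the doses and 212 for low-dose STW5 against omeprazole. With an estimated correlation camera called 0 lists in all 10 comparisons, and between 0 and 8 had an unadjusted p under 0.05. With 20 arrays, none averaged, 0 genes changed for low-dose STW5 against sham and 1136 against omeprazole, while the other counts of genes were 4619 with surgery, 6066, 1497 and 3988 for low-dose STW5, high-dose STW5 and omeprazole against untreated, and 4728 between the doses. With a replicate block on 20 arrays these were 5 and 1150, with 4986 between the doses, 77 for high-dose STW5 against omeprazole and 1 list for omeprazole against sham. With group means subtracted, same-number arrays of different groups correlated by -0.32 to 0.58 (median 0.081) and others by -0.52 to 0.64 (median -0.0066). In 28 of 80 cases the closest array of another group had the same number, but numbers are slide positions too. So neither this nor the replicate block settles a pairing. Without the slide 3 genes 35 genes and 11 lists were called for omeprazole against sham and 45 genes for low-dose STW5 against omeprazole. The set held 136 and 138 of the genes called there, and 42 and 145 genes outside it lost their call too. Without sham replicate 2 and the slide 3 genes 71 genes and 15 lists were called for omeprazole against sham. Leaving out each sample in turn gave 0 to 90, 405 to 1468 and 169 to 329 genes for low-dose STW5, high-dose STW5 and omeprazole against sham, 414 to 2037 for high-dose STW5 against untreated, 926 to 4069 between the doses, and 5 to 22 and 164 to 783 for high-dose and low-dose STW5 against omeprazole. The lists called ranged from 4 to 14 and 0 to 14 for low-dose STW5 and omeprazole against sham, 6 to 18 for high-dose STW5 against untreated and 5 to 17 for low-dose STW5 against omeprazole. For surgery the range was 3361 to 4672 genes, for low-dose STW5 and omeprazole against untreated 3597 to 5019 and 2696 to 4121, and the return was 78.3% to 93.4% for low-dose STW5, 33.3% to 43.7% for high-dose STW5 and 60.5% to 75.6% for omeprazole. Between 61.5% and 70.5% of features were well above background, and genes below that are not measured here.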
